A study of Glehnia littoralis with 3 samples.

How the data were processed

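Small RNA was sequenced from young leaves of *Glehnia littoralis*, a coastal medicinal herb of the carrot family (Apiaceae), in 3 libraries. Per the labels, 1 library came from unstressed control plants, 1 from plants held in 250 mM NaCl for 1 h, and 1 from salt-treated plants returned to distilled water for 1 h. Each condition therefore had 1 library. Whether a library pooled several plants is not given in the sources used here.

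The deposited values are raw read counts, 1 for each distinct sequence (tag) of a library, with the tag's length beside it. The authors had collapsed identical reads before deposit, and the tags were 18 to 47 nt long in every library. The submitters' processing notes name CASAVA and Bowtie, with no version or role. Adaptor removal, quality filters, genome build and annotation are not given in the sources used here. Such steps set which lengths and sequences remain, so length shares describe the deposited tags. PCR reads without molecular identifiers are not independent molecules, so all intervals and floors here cover counting error only.

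From the counts, RPM values, which scale reads to a common total, were computed against all deposited reads of a library. The totals were 8865179 reads for control, 10728444 for salt and 10926370 for recovery. A count of 0 allows up to 3 reads, or 0.338, 0.280 and 0.275 RPM in these libraries. A level has an exact Poisson interval and a share an exact Clopper-Pearson interval, both at 95%. No reference genome was used, so tags have no genomic positions, and precursor hairpins were not examined.

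A tag was given to a conserved miRNA family when it was 19 to 24 nt long and began at the same base as a known mature sequence. At most 1 substitution over the shared length and a length difference of at most 2 nt were allowed. The list held 50 mature sequences of 30 families and was written from general knowledge of plant miRNAs. The list was fixed before the data were examined, as were 9 lists of families by function, 6 tRNA sequences, a 5.8S rRNA sequence and miRNAs of 6 families known from Brassicaceae. These sequences, the passenger strand and TAS3 sequences and the animal markers described below were likewise written from general knowledge, and none was checked against a database release. In tests on simulated tags, all 1190 tags made from the list and other reference miRNA sequences, such as those of Brassicaceae, were given the right family. These tags had at most 1 substitution and no shifted start, which the rule accepts by design. The test therefore checks the matching code and the separation of families only.

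With 1 library per group no test between conditions was possible, no spread between plants could be estimated and no p-value is given. Ratios between libraries compare those libraries, not the conditions in general. Each ratio has an exact conditional binomial 95% interval. A family was counted as higher or lower when it had at least 100 reads in both libraries together, a ratio of at least 2 and an interval that excluded no difference. No ratio is given where both libraries held 3 reads or fewer. The rule was tried on simulated counts, which carried counting error alone and no spread between libraries. A cut-off of 2-fold largely fixes the share of 2-fold changes called. For salt against control, the rule called all 100 tags changed 4-fold of 6965 tags, 52% of those changed 2-fold, and 1 unchanged tag. For recovery against control it called all of the 4-fold tags, 51% of the 2-fold tags and 1 unchanged tag among 6799, and for recovery against salt all of the 4-fold tags, 51% and 0 among 6998.

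For each list with at least 3 measured families, the median log2 ratio was set among 10000 random lists of 20 to 22 nt tags matched on mean abundance. This percentile describes these libraries only. The families named are the 10 most abundant, each family past the size rule, and 2 to 4 examples per list. The unmatched tags named are the 5 most abundant and the 3 most higher and 3 most lower ones per comparison, with at least 50 RPM in one library and 3 reads in the other. This rule was also fixed before the data were examined.

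A panel of 40 animal miRNA markers was added after a tag resembling an animal miRNA had been seen in the salt library, and before the other markers were looked up. It held 16 markers shared by most bilaterian animals, 12 known from protostomes (the branch with insects and mites) and 12 known from vertebrates. A tag was called near-exclusive to a library when it reached 2 RPM there and at least 20 times its level in each of the other libraries, after adding 0.1 RPM. This definition was also made after seeing the data. Sequences of these tags, and of the unmatched tags ranked by ratio, are not printed because their organism is not established.

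The alternatives comprised 12 settings for the families, fixed before the data were examined. They covered matching, minimum reads, the size of the ratio and scaling. Scaling was to conserved families, to tags of 18 to 26 nt, by edgeR 4.0.16 TMM factors or by DESeq2 1.42.0 size factors. The TMM and DESeq2 factors were themselves computed from the conserved-family counts. Like the scaling to conserved families, they therefore assume that those families did not shift together. A further 2 scalings were added after seeing the data. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, scaling factors with R 4.3.3, and plots with matplotlib 3.10.9.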

Results

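Small RNA of young *Glehnia littoralis* leaves was profiled in unstressed plants, after 1 h in 250 mM NaCl, and after 1 h of recovery in distilled water. The series set out to identify miRNAs of this species and to follow them under salt. The libraries held 8865179 (control), 10728444 (salt) and 10926370 (recovery) reads, in 2470954, 2647628 and 2738531 distinct tags. Each condition had 1 library, so no difference below has a replicate check, and the intervals cover counting error only.

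The 24 nt class was the most abundant length in all 3 libraries when all tags were counted. Among tags with at least 2 reads, 21 nt exceeded 24 nt in control (17.2% against 15.3%). It took 22.06% of control reads (95% Clopper-Pearson interval 22.03 to 22.09), 18.99% of salt reads and 22.5% of recovery reads. Of these 24 nt reads, 44.0%, 43.8% and 45.9% began with A. In plants this class consists largely of small interfering RNAs that guide DNA methylation. The 21 nt class, the usual length of plant miRNAs, took 15.04% of control, 10.6% of salt and 12.9% of recovery reads. Reads of 27 nt or longer took 22.6% in control, 36.5% in salt and 33.0% in recovery.

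**Figure D1:**
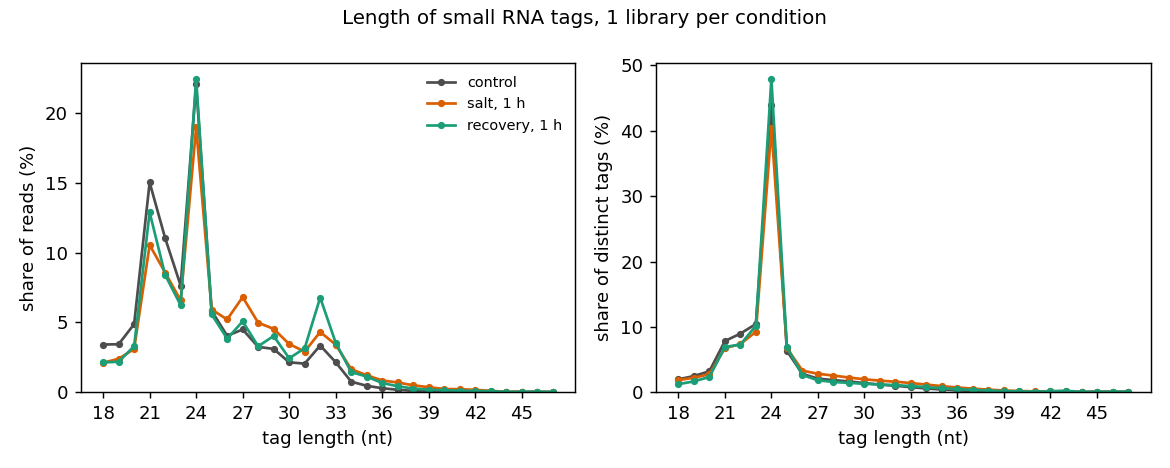
Share of reads (left) and of distinct tags (right), in percent, at each tag length in nt, with 1 line per library. With all tags counted, the 24 nt peak is the highest in every library, and the salt library has 10.6% of its reads at 21 nt against 15.04% in control. Without the 10 most abundant tags of each library, the 21 nt shares are 10.04% in salt and 12.5% in control.

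Distinct tags found in all 3 libraries made up 5.69% of the 6520021 tags seen in any library, and held 72.2% of control, 69.4% of salt and 74.6% of recovery reads. Fragments of 6 tRNAs stood at 8480 RPM in control, 5608 RPM in salt and 13865 RPM in recovery. The largest part came from the glutamate tRNA, with 4142, 2496 and 8023 RPM. A chloroplast histidine tRNA gave 137 RPM in control, 373 RPM in salt and 430 RPM in recovery. Fragments of 5.8S rRNA stood at 6169, 6822 and 6013 RPM, an order of libraries that differs when 1 substitution is allowed (12597, 10996 and 9827 RPM). The 6 Brassicaceae miRNA families had 0 reads in every library, which allows up to 0.338, 0.280 and 0.275 RPM.

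Of the 30 conserved miRNA families looked for, 25 had at least 1 read and 20 were measured. The families together took 1.97% of control, 1.27% of salt and 1.74% of recovery reads. These totals depend on the rule of a shared start. With starts within 2 nt accepted, miR166 alone had 23204 RPM in control, 14197 RPM in salt and 23619 RPM in recovery. miR166, which targets class III HD-ZIP transcription factors of leaf polarity, was the most abundant, with 10613 RPM in control, 5263 RPM in salt and 8282 RPM in recovery. miR159, a regulator of GAMYB-type MYB factors, followed with 3600, 2267 and 2654 RPM. miR396, which targets growth-regulating factors, had 1832, 1423 and 1910 RPM. miR156, which targets SPL factors of the juvenile phase, had 1508, 1159 and 1709 RPM. miR168, which targets AGO1 of the silencing complex, had 963, 1503 and 1725 RPM. The next in abundance were miR403 (282.3, 394.1 and 376.6 RPM), miR169 (155, 129 and 131 RPM), miR319 (221.5, 45.5 and 130 RPM), miR167 (112, 142 and 111 RPM) and miR162 (93.96, 75.1 and 85.3 RPM).

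Salt against control asked which miRNAs differed after 1 h in NaCl. 5 of 20 measured families passed the size rule, 1 higher and 4 lower in salt. miR399, a phosphate-starvation miRNA that targets the PHO2 ubiquitin-conjugating enzyme, was 2.65-fold higher (log2 ratio 1.40, interval 1.22 to 1.59). miR319, which targets TCP factors of leaf growth, was 4.87-fold lower (log2 ratio -2.28, interval -2.43 to -2.14). miR858, a regulator of MYB factors, was 3.11-fold lower, miR160, which targets auxin response factors, 2.56-fold lower, and miR166 2.02-fold lower. miR408, a copper-responsive family, missed the rule at a log2 ratio of 0.93 (interval 0.73 to 1.14), as did miR168 at 0.64 and miR171 at -0.96. miR408 passed as higher under each of the 4 other planned scalings and with the most abundant tag of each family alone, miR168 with conserved-family and TMM scaling, and miR171 as lower with no substitution or at most 2 substitutions.

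Among the growth and leaf development families, 0 of 7 measured were higher, 2 were lower (miR319 and miR166) and 5 passed in neither direction, such as miR159 at -0.67 and miR396 at -0.36. The list median was -0.67, at percentile 25.5 of random lists, or 5.69 against random 21 nt tags starting with T. In the auxin list, 1 of 4 was lower (miR160) and 3 were neither, with miR167 at 0.34 and miR393 at -0.64, and the median of -0.65 lay at percentile 34.8, or 10.7 against random 21 nt tags starting with T. The small RNA pathway list holds miR162 (DCL1), miR168 (AGO1) and miR403 (AGO2). None of the 3 passed the rule, and their log2 ratios were -0.32, 0.64 and 0.48, but miR168 (1.28) and miR403 (1.12) passed as higher with conserved-family scaling. Its median of 0.48 lay at percentile 97.45. Of families reported as higher under salt in *Arabidopsis*, 0 of 11 were higher, 2 were lower and 9 were neither, with a median of -0.40 at percentile 72.3, or 27.3 against random 21 nt tags starting with T. The copper list had miR398 at 0.45 beside miR408, and miR398 too passed as higher with conserved-family scaling (1.08), and miR399 was the only measured member of the phosphate or sulfate list. In the MYB list miR858 was lower and miR159 neither, miR169 of the NF-Y list stood at -0.27, and the disease resistance list had 0 measured families. Conserved-family scaling turned the *Arabidopsis* salt median to 0.23 and moved the development, auxin and small RNA pathway medians to -0.033, -0.018 and 1.12. This scaling leans on miR166, which held 53.8% of conserved-family reads in control and 41.4% in salt. Without miR166 the conserved families together had a log2 ratio of -0.292, against -0.63 with it. Scaled to the conserved families without miR166, miR168, miR403 and miR398 would all fall short of the size rule, so these gained calls depend on miR166. The shifts of these medians depend on it in part. 

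The salt library also held more sequences of protostome animal type. Protostome markers stood at 78.6 RPM in control, 2021 RPM in salt and 443 RPM in recovery. Tags near-exclusive to the salt library took 9.22% of its reads. The split of 1 higher and 4 lower depended on scaling. It was 5 and 2 when scaled to conserved-family reads, 2 and 3 when scaled to reads of 18 to 26 nt, 3 and 2 with TMM factors and 2 and 3 with DESeq2 size factors. These scalings moved the median log2 ratio by 0.63, 0.29, 0.50 and 0.34. miR319 and miR858 remained lower and miR399 higher under all of them, whereas the miR166 call ended under each of them and when 5′ starts within 2 nt were accepted (-0.71). It also ended with exact matches only (-0.63) and with the most abundant tag alone (-0.62), both of which leave out the 1-substitution tag TCGGACCAGGCTTCATTCCTC. miR160 did not pass with conserved-family or TMM scaling. The miR399 value rests on tags with 1 substitution to the list, chiefly TGCCAAAGGAGAATTGCCCTG and TGCCAAAGGAGAGTTGCCCTC, and exact matches numbered 0, 1 and 2 reads in control, salt and recovery. Exact matches were also few for miR398 (0, 0 and 1 reads) and miR172 (6, 6 and 2 reads).

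**Figure D2:**
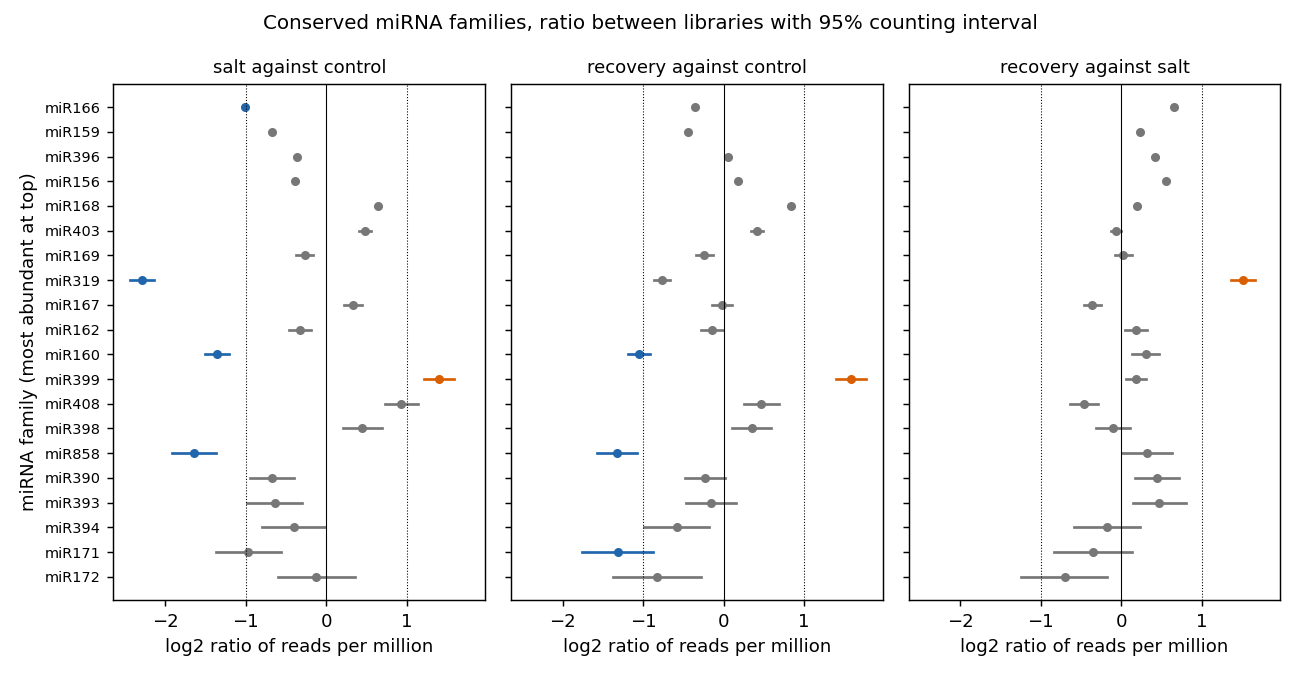
Log2 ratio of RPM for the 20 measured families in the 3 comparisons, with 1 library per condition. Points are ratios, lines 95% counting intervals, dotted lines a 2-fold difference, and orange and blue mark families past the size rule as higher and lower. miR319 stands at -2.28 in salt against control and at 1.51 in recovery against salt. Scaling to conserved-family reads moves the median of salt against control by 0.63.

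Recovery against control asked which differences were present 1 h after the return to distilled water. 4 of 20 families passed, 1 higher and 3 lower in recovery. miR399 was 2.99-fold higher (log2 ratio 1.58, interval 1.40 to 1.77). miR858 was 2.502-fold lower (-1.32, interval -1.57 to -1.08), miR171, which targets GRAS factors, 2.48-fold lower (-1.31, interval -1.75 to -0.88) and miR160 2.07-fold lower (-1.05, interval -1.19 to -0.91). miR168 stood at 0.84, miR319 at -0.77 and miR166 at -0.36, all short of the rule. The miR166 sign turned with 5′ starts within 2 nt (0.026) and with its most abundant tag alone (0.029). With the most abundant tag of each family alone, miR171 stood at -0.81 and no longer passed.

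The small RNA pathway list had a median of 0.42 at percentile 98.0, with 0 of 3 families past the rule. The growth and leaf development list had 1 of 7 lower (miR171) and 6 neither, such as miR156 at 0.18 and miR159 at -0.44, with a median of -0.44 at percentile 34.9. The auxin list had 1 of 4 lower (miR160) and a median of -0.20 at percentile 83.1. The *Arabidopsis* salt list had 1 of 11 lower and 10 neither, with a median of -0.24 at percentile 75.1. Conserved-family scaling moved the small RNA pathway, development, auxin and *Arabidopsis* medians to 0.59, -0.26, -0.017 and -0.061. The copper families stood at 0.35 (miR398) and 0.47 (miR408), miR169 at -0.24, and in the MYB list miR858 was lower. Protostome animal markers were 443 RPM here against 78.6 RPM in control.

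The recovery split of 1 higher and 3 lower became 2 and 2 with conserved-family, 18 to 26 nt and TMM scaling, where miR168 passed and miR160 did not, and 1 and 2 with DESeq2 size factors. Those scalings moved the median by 0.18, 0.21, 0.31 and 0.15. Calls of both comparisons against control shared miR399 among the higher families, where independent lists would share 0.05, and miR160 and miR858 among the lower, where independent lists would share 0.6. Simulated unchanged libraries shared 0 calls on average, but these carry counting error alone and leave out any spread between libraries. Both comparisons use the same control library, which cannot be split, so part of the sharing may come from it.

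Recovery against salt asked what differed between stressed and recovering plants. Only miR319 passed among 20 families, 2.86-fold higher in recovery (log2 ratio 1.51, interval 1.37 to 1.67), and it passed under every scaling tried. miR166 stood at 0.65, miR156 at 0.56, miR408 at -0.46 and miR172, which targets AP2-type factors of flowering time, at -0.70. The growth and leaf development list had 1 of 7 higher and a median of 0.42 (percentile 86.2, or 96.4 against random 21 nt tags starting with T), the auxin list 0 of 4 and 0.37 (84.0), the small RNA pathway list 0 of 3 and 0.18 (55.6), and the *Arabidopsis* salt list 1 of 11 and 0.23 (69.7). Among the smaller lists, miR398 stood at -0.10, miR399 at 0.18, miR858 at 0.31 and miR169 at 0.03. Scaling to conserved-family reads moved the median by -0.46 and turned these 4 medians to -0.031, -0.085, -0.27 and -0.23, and miR172 then passed as lower, a split of 1 and 1. Protostome markers were at 2021 RPM in salt and 443 RPM in recovery.

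Among tags of 18 to 26 nt outside the family list, TTTCGGACCAGGCTTCATTCC was the most abundant by mean RPM, with 10076 RPM in control, 7711 RPM in salt and 13484 RPM in recovery. It overlaps the miR166 sequence from a start 2 nt upstream, and 54.3%, 62.9% and 64.9% of miR166 reads had a shifted start when starts within 2 nt were accepted. CCCAGTCCCGAACCCGTCGGCT, whose source is not established, was higher than it in control and had 11623, 4120 and 12035 RPM, a log2 ratio of -1.50 in salt against control and 0.05 in recovery against control. The other 3 of the 5 most abundant unmatched tags overlap it. Of 736 unmatched tags of 20 to 24 nt that reached 50 RPM, 75 were at least 2-fold higher and 197 at least 2-fold lower in salt than in control. These tags were compared per total reads only, and overlapping tags were counted separately. The 3 with the highest ratios were 23 to 24 nt long, at 4317-, 3500- and 2354-fold, and all were near-exclusive to the salt library. The 3 with the lowest were 61.2-, 40.4- and 19.9-fold lower. In recovery against control the 3 highest were 7.88-, 5.74- and 4.87-fold higher, of which 1 matched the animal marker miR-184, and the 3 lowest 84.4-, 71.2- and 13.5-fold lower. The tags at 84.4- and 71.2-fold were the same as those at 40.4- and 61.2-fold in salt, and were near-exclusive to the control library. In recovery against salt the 3 highest were 10.6-, 10.5- and 10.4-fold higher, and the 3 lowest 1618-, 1289- and 985-fold lower. These 3 lowest were the same tags, near-exclusive to the salt library, that stood at 3500-, 2354- and 4317-fold in salt against control. By the same 2-fold count, 15 of 689 tags were higher and 115 lower in recovery against control. In recovery against salt, 117 of 633 were higher and 80 lower.

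**Figure D3:**
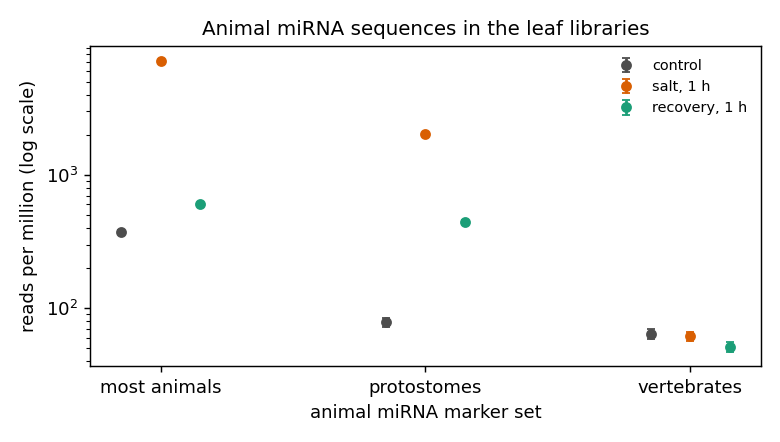
RPM, on a log axis, of 3 sets of animal miRNA markers in each library. Points are sums over a set and bars 95% Poisson intervals, which are smaller than most points. Protostome markers stand at 78.6 RPM in control, 2021 RPM in salt and 443 RPM in recovery, and vertebrate markers at 64.2, 61.9 and 51.4 RPM.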

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

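The marker, 24 nt near-exclusive tag, dilution, long-read, single-family, combined and sequencing-error tests below were chosen after the results, or the length shares they rest on, had been seen. The test of another plant was set before its value was seen.

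Protostome and bilaterian animal miRNA marker sets, which lie outside the plant families compared, were above the control level in both other libraries. Protostome markers reached 2021 RPM in salt and 443 RPM in recovery against 78.6 RPM in control, and bilaterian markers 7149 and 605 RPM against 373 RPM. The most abundant were miR-10 (306, 6325 and 335 RPM in control, salt and recovery), miR-276 (37.4, 1212 and 134 RPM) and bantam (29.7, 588 and 249 RPM). Tags near-exclusive to the salt library, 2898 in number, took 9.22% of its reads, against 0.469% for control and 0.0101% for recovery.

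For the near-exclusive salt tags, a vertebrate source is argued against by the median log2 ratio of -0.0033 over 8 vertebrate markers. A protostome source stays open: all 12 protostome markers were at least 2-fold higher in salt than in control, but near-exclusive tags held only 0.258% of their salt reads, and their median log2 ratio over recovery, 2.39, is short of the 20-fold level that defines these tags. Of bilaterian marker reads in salt, near-exclusive tags held 88.2%, from 3 of 16 markers, and it was a tag of this kind that prompted the panel; miR-31 (8.46 RPM in control, 0.932 RPM in salt) and miR-100 (2.71 and 1.40 RPM, interval of the log2 ratio -1.99 to 0.037) were lower in salt. Plant small interfering RNAs stay open too, since the 24 nt share of 4.37% compares with 7.71% in all salt tags of at least 2 RPM and with 5.67 and 7.66% in the near-exclusive tags of control and recovery. Whether animal RNA entered on the leaf or in handling, and whether its load differed with treatment, was not tested.

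Conserved miRNA families together had a log2 ratio of -0.63 in salt against control. This total leaves out miR166 reads with a shifted start, and with starts within 2 nt accepted miR166 stood at -0.71. With near-exclusive tags left out, 24 nt reads differed by -0.245, less than the conserved families did. This cannot settle dilution by foreign RNA as the whole cause. Foreign 24 nt reads outside the near-exclusive tags would stay in the count and hide part of a dilution. Neither miR166 (-0.292 without it) nor reads longer than 26 nt (-0.348 when scaled to reads of 18 to 26 nt) accounted for the conserved-family difference alone. Both together left -0.0054, and miR166 with the 24 nt fall left -0.047. Leaving out miR166, which was lower, and rescaling to a length class that was lower in salt each raise the value by construction. The remaining families differed in both directions, such as miR168 at 0.64 and miR159 at -0.67, so a sum near 0 does not account for each family. These combined values divide the difference into parts without ranking them, and the parts overlap, since 56.3% of near-exclusive salt reads were 27 nt or longer. A salt effect on miRNAs was not tested, because condition and library coincide.

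Within miR166, the tag TCGGACCAGGCTTCATTCCTC stood at 0.682 of the reads of TCGGACCAGGCTTCATTCCCC in control, 0.265 in salt and 0.268 in recovery. Against control, the former was 3.96-fold lower in salt and 2.49-fold lower in recovery, while the latter had log2 ratios of -0.62 and 0.03. Sequencing errors at a fixed rate in the more abundant tag would give equal ratios, and the highest ratio was 2.57 times the lowest. These are the values of the pattern itself and not separate evidence. An error rate that differs between libraries was not tested. For another plant's RNA in the control library, 6.67% of 30 tags of other families with 1 substitution showed a similar excess in control, with an interval of 0.818 to 22.1%. This share met the level set beforehand for no such RNA, and the interval lay below the level set for such RNA. The interval also ran past the former level, so the explanation was not settled. A second miR166 gene with its own response to salt, or plants of differing genotype, may also give this pattern and was not tested.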

How the results depend on the processing

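Of the family settings, 2 (totals without near-exclusive tags, and reads of 24 nt) were chosen after seeing the data. No called family changed direction under any setting that gave a value. miR399 had no value with exact matching, where it held 0, 1 and 2 reads. No paired analysis was possible because each group holds 1 library, and for the same reason no library could be left out. Depth limits families under 100 reads, and the cause of the shifts was not tested beyond the construction of each setting. Without near-exclusive tags, or scaled to 24 nt reads, salt against control gave 2 higher and 3 lower.

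At a ratio of 1.5, 11 families passed in salt against control, 7 in recovery against control and 3 in recovery against salt. With no minimum of reads, salt against control gave 7 families, and recovery against salt gave 2, as it did with conserved-family scaling (2).

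Conserved-family scaling moved list medians as follows, in the order salt against control, recovery against control and recovery against salt. The auxin list had -0.018, -0.017 and -0.085, the development list -0.033, -0.26 and -0.031, the small RNA pathway list 1.12, 0.59 and -0.27, and the *Arabidopsis* salt list 0.23, -0.061 and -0.23. With random lists of 21 nt tags starting with T, percentiles of the auxin, development, small RNA pathway and *Arabidopsis* lists were 10.7, 5.69, 95.7 and 27.3 in salt against control, 59.8, 26.5, 97.7 and 61.1 in recovery against control, and 88.8, 96.4, 68.98 and 87.0 in recovery against salt.

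Length shares are given for control, salt and recovery. For 21 nt they were 7.83, 6.74 and 6.92% of distinct tags, 17.2, 11.5 and 14.4% with at least 2 reads, 12.5, 10.04 and 10.5% without the 10 most abundant tags, and 15.2, 10.6 and 13.1% without tRNA and 5.8S rRNA fragments. With at least 2 reads, 21 nt exceeded 24 nt in control. For 24 nt the same settings gave 43.9, 40.5 and 47.9%, then 15.3, 13.4 and 15.9%, then 24.001, 20.3 and 25.2%, and then 22.3, 19.2 and 22.8%.

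Tags found in all 3 libraries were 18.5% of distinct tags with at least 2 reads and 5.65% after thinning to the smallest library. Allowing 1 substitution gave tRNA fragments at 13741, 8864 and 21194 RPM and rRNA fragments at 12597, 10996 and 9827 RPM.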

Other observations

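The passenger strand of miR168 stood at 38.1 RPM in control, 33.6 RPM in salt and 26.5 RPM in recovery, or 3.81, 2.18 and 1.52% of mature and passenger reads together. The TAS3 small interfering RNA that targets auxin response factors had 8.80, 5.03 and 4.76 RPM, a log2 ratio of -0.81 in salt against control (interval -1.33 to -0.29). Its trigger miR390 had 28.9, 18.2 and 24.6 RPM. Conserved-family scaling shifts salt against control by 0.63, which took the miR390 log2 ratio from -0.67 to -0.033. The same shift would bring the TAS3 interval across no difference. The miR393 passenger strand had 5.19, 1.86 and 5.22 RPM.

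The animal markers kept no fixed ratio between salt and recovery. Bantam stood at 588 and 249 RPM and miR-276 at 1212 and 134 RPM, while miR-12 was higher in recovery (3.17 and 13.9 RPM).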
